A study of Mus musculus with 6 samples.

How the data were processed

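Single cells of mouse kidney were sorted into 6 plates and sequenced with Smart-seq2. Per the labels, each plate mixes cells of 1 healthy mouse, 1 mouse at day 2 and 1 mouse at day 10 of unilateral ureteric obstruction (UUO), prepared by enzymatic digestion and cell sorting. For each plate the authors deposited a table of raw read counts per gene and well, a table of raw read counts per spike-in RNA (92 ERCC sequences) and a layout with the text label of each well. The deposited values are whole counts, not normalized. The submitters' processing notes name STAR and mm10 without a version, and the tool that counted reads, the annotation and any filter are not stated. Strandedness is not stated, and reads from genes that overlap on opposite strands were taken as counted. The layout gives each well a gate (mesenchyme or endothelia), a condition and a number from 1 to 4, and marks 12 control wells.

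In every plate a condition and gate fill the same 4 columns of wells, so a condition cannot be told apart from its plate columns. The number is 1 on plates 1 and 2, 2 on plate 3, 3 on plate 4 and 4 on plates 5 and 6. It was assumed to mark the mouse of each condition, because the layout names no mouse otherwise. This unit was chosen in place of the plate after the layouts were read, and sums per plate are an alternative. The count tables hold 24490 entries, of which 771 share 279 symbols. Entries of 1 symbol were added, leaving 23998 symbols, so copies of a gene under 1 symbol are not told apart. Members of families of similar sequence, such as Serpina3n and Serpina3g or Ren1 and Ren2, can share reads. Rn45s took 1.91% and Malat1 1.50% of reads in kept cells. Gene positions are from the GRCm38.p6 (mm10) annotation, which may differ from the one the authors used.

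Cells were kept with at least 1000 genes and 20000 reads on genes, which left 2235 of 2292 sorted wells (344, 380, 380, 378, 377 and 376 on plates 1 to 6). Control wells held a median of 3264 reads on genes (251 to 30393). Counts were scaled per cell and log-transformed with scanpy 1.11.5, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, seed 0) gave the clusters. Clusters were called by cell type markers fixed before the data were examined, where at least 3 markers were detected in at least 50% of a cluster's cells at 2 times the mean over clusters. A cluster whose 10 leading genes held more markers of another subclass stayed unnamed. That naming rule, and the glomerular-marker group, which joins the clusters with glomerular endothelial markers (3, 4 and 8, of which 8 is led by Apln, Esm1 and Cxcr4), were set after the clusters were seen. A cell counted as mesenchymal-like or endothelial-like when its cluster and its gate gave the same class, which held for 2009 cells. Doublets were not called, and possible mixed wells were left out in an alternative.

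Counts were summed per class, condition and number, with at least 10 cells per sum. Genes were filtered with filterByExpr and scaled with TMM, and edgeR 4.0.16 (R 4.3.3) tested each comparison with quasi-likelihood F tests in a fit of all sums of a class (12, and fewer in some subclasses) with number as a block. Same-numbered sums of different conditions shared deviations from their condition's mean only weakly across genes (r from 0.00277 to 0.275), so the block rests on the shared plates. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Beside counts of 0, the number of genes at an unadjusted p under 0.05 is given. A share of about 0.05 of the genes tested would reach that with no change at all. A change is a log2 fold change with its SE, computed as the size of the change over the square root of F. CPM of named genes are TMM-scaled means over 4 sums with their SD, and levels of gate markers, tubule transcripts and pooled subclasses are unscaled CPM. Fold changes are not given where the healthy level was near 0. The difference between classes was tested as an interaction in a fit of all 24 sums with number as the block. Counting intervals and limits cover counting error only, since reads carry no molecular identifiers.

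Genes were named by a rule fixed before the data were examined: per comparison, up to 8 genes of largest change in each direction among those past the threshold with a mean log2 CPM of at least 4 and 1 sign in every number, the 2 to 4 members of smallest p of described lists, and always Acta2, Col1a1, Pdgfrb, Pecam1 and Havcr1. Genes with Gm-number, Rik and -ps names were passed over. For the genes of largest change, 1 sign in every number was thus a condition of naming and not a separate result. Some genes that met this rule are not reported here. Differences between classes used the 5 largest in each direction. The 31 gene lists were fixed at the same time and tested with camera (limma 3.58.1, preset correlation 0.01), with camera under an estimated correlation and with fry, adjusted over all lists and comparisons of a class. Counts for a list are given over all genes and adjusted over the list alone.

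Shares of subclasses among the kept cells of a gate, cells with reads of at least 3 of 10 cell cycle genes, and the median log2 ratio of gene reads to ERCC reads in cells with at least 100 ERCC reads were compared by two-sided exact sign-flip tests over the 4 numbers (16 flips, smallest p 0.125, so that 0.05 cannot be reached). Over the 6 plates there are 64 flips and a smallest p of 0.03125, but plates 1 and 2 and plates 5 and 6 share numbers. An edgeR test of cell numbers per subclass was added after the shares were seen. Concordance of the day 2 and day 10 changes was compared with 20 simulated data sets without an injury effect. Tests on simulated data with known folds, run on sums of the same depth and spread, recovered 15.6% of genes at a 2-fold change, 75.4% at 4-fold and 91.0% at 8-fold for mesenchymal-like cells at day 2, with 5 of 13551 unchanged genes called. Changes were planted only in genes with a mean log2 CPM of at least 4. For the difference between classes at day 2 and day 10, 4.48% and 4.17% were recovered at 2-fold and 37.7% and 30.4% at 4-fold.

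The alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, no block, leaving out each plate, at least 2000 genes or at least 500 genes and 5000 reads per cell, at least 20 cells per sum, cells thinned to 20000 reads, cells of mixed markers left out (1 read of at least 3 markers), other list tests, Leiden resolutions 0.5 and 1.5, and other limits for the proliferation and ERCC measures. Added after the data were seen were sums per plate, leaving out number 1 or number 4, the mouse as block, all cells of a gate, mixed markers at 100 CPM, leaving out plate rows C and D of plate 1, leaving out fibroblast-like cells, sign flips over plates, and the tests of glomerular-marker, arterial-like and peritubular capillary-like cells. Subclasses were tested where at least 3 sums per condition held 10 cells, which fibroblast-like and mesangial-like cells did not reach, nor pericyte-like and peritubular capillary-like cells at day 10. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.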

Results

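The series profiled single cells of mouse kidney, sorted from digested tissue and sequenced with Smart-seq2, a plate method that reads whole transcripts of one cell per well. Its title names mesenchymal and endothelial cells in renal injury as the subject. The injury was unilateral ureteric obstruction (UUO), ligation of a ureter, which damages the tubules of that kidney and leads to fibrosis. Each of 6 plates held cells of 3 mice, namely a healthy mouse, a mouse at day 2 of UUO and a mouse at day 10 of UUO, from a mesenchyme gate and an endothelia gate. The deposited well layouts carry a number from 1 to 4 (plates 1 and 2, plate 3, plate 4, plates 5 and 6), which was taken to mark the mouse of each condition, so that n = 4 unless another number is given. Of 2292 sorted wells, 2235 held a cell of at least 1000 genes and 20000 reads. The plates held from 116992491 to 142898570 reads on genes, and the median cell of a gate and condition held from 312617 to 447221 reads.

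Clusters of cells with mesenchymal or endothelial markers held 319 healthy, 316 day 2 and 319 day 10 mesenchymal-like cells, and 352, 347 and 356 endothelial-like cells. Their counts were summed per number and condition, and each sum held from 16394911 to 42733590 reads on genes in mesenchymal-like cells and from 21080683 to 50180686 in endothelial-like cells. Pecam1, an adhesion molecule of endothelium, stood at 2305 CPM (read counts scaled by the total of a sum) in healthy endothelial-like cells and 1.03 CPM in healthy mesenchymal-like cells. Pdgfrb, the platelet-derived growth factor receptor of mural cells and fibroblasts, stood at 1049 CPM in mesenchymal-like and 1.0 CPM in endothelial-like cells. RNA of tubule cells was present in both classes and differed between conditions. Kap, an abundant transcript of the proximal tubule, had a mean of 129, 25 and 0.833 CPM in healthy, day 2 and day 10 mesenchymal-like cells and 167, 37.9 and 2.46 CPM in endothelial-like cells. Havcr1 (kidney injury molecule 1), which injured proximal tubule cells make, had 0.00652, 5.59 and 0.282 CPM in mesenchymal-like cells and 0, 9.16 and 0.00504 CPM in endothelial-like cells.

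The comparison of day 2 UUO with healthy kidneys asks how mesenchymal cells respond early to obstruction. Itih4, an inter-alpha-trypsin inhibitor heavy chain of the acute phase (chromosome 14, 30886476 to 30901986 of mm10), stood at 1037 ± 231 against 15.6 ± 14.9 CPM (SD, n = 4), a change of 6.42 ± 0.54 on the log2 scale (SE; edgeR adjusted p = 0.000533). Serpina3n, a serine protease inhibitor of the acute phase, stood at 235 ± 73.5 against 0.889 ± 1.61 CPM (adjusted p = 0.00181). Spp1, which encodes osteopontin (chromosome 5, 104435111 to 104441053), rose by 6.22 ± 0.41 log2, adjusted p = 0.000197, and Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874737), by 6.08 ± 0.78 log2, adjusted p = 0.00468. Clu, a secreted chaperone, rose from 179.9 to 1207 CPM (2.78 ± 0.23 log2, adjusted p = 0.000533), and Osmr, a subunit of the oncostatin M receptor, by 2.69 ± 0.36 log2, adjusted p = 0.0060. The other genes of largest positive change were Rasl10b (4.21 ± 0.43) and Fgl2 (3.23 ± 0.32). The genes of largest negative change were Ccdc80, a secreted matrix-binding protein, at -1.74 ± 0.20, the kinase gene Prkcd at -1.72 ± 0.16, Ogn, a small leucine-rich proteoglycan, at -1.63 ± 0.27, and Angptl2 (-1.48 ± 0.19), Ntrk3 (-1.36 ± 0.17), Slc29a1 (-1.31 ± 0.21), Grb14 (-1.21 ± 0.19) and Ramp1 (-1.06 ± 0.20). Values for Col1a1 (0.43 ± 0.46 log2, adjusted p = 0.827), Acta2 (-0.16 ± 0.10 log2, adjusted p = 0.632) and Pdgfrb (0.14 ± 0.12 log2, adjusted p = 0.755) did not pass. All changes named here had 1 sign in 4 of 4 numbers, apart from those of Col1a1, Acta2 and Pdgfrb. In all, 86 of 13751 genes tested passed, 68 higher and 18 lower at day 2. Of 17 matrix protease and inhibitor genes, 2 rose, 0 fell and 15 did not pass. Adjusted over the list alone, 5 rose and 0 fell, and the median change was 0.38 (camera adjusted p = 0.00136, and adjusted p = 0.112 with an estimated correlation), with Plat, the tissue plasminogen activator, at 1.7 ± 0.13. None of the 8 complement genes passed over all genes, 6 rose adjusted over the list alone, and their median change was 0.77 (adjusted p = 1.86e-07, and adjusted p = 0.0663 with an estimated correlation). Of 31 fixed lists, 10 passed camera with its preset correlation, 6 higher and 4 lower, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. The count of genes was 53 without the block on number, 38 without number 1, 32 without number 4, 35 without plate 4, 49 without plate 3 and 53 without plate 2.

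By day 10, the comparison with healthy kidneys asks which mesenchymal changes go with later obstruction, when fibrosis develops. Col1a1, the alpha 1 chain of type I collagen (chromosome 11, 94936224 to 94953042), stood at 895 ± 598 against 152 ± 145 CPM (2.98 ± 0.47 log2, adjusted p = 0.0117), Tnc, the matrix glycoprotein tenascin C, at 315 ± 196 against 7.63 ± 11.7 CPM (6.16 ± 1.19 log2, adjusted p = 0.029), and Col12a1 rose by 2.46 ± 0.34. Of 25 fibrillar collagen and matrix genes, 12 rose, 1 fell and 12 did not pass. With p adjusted over the list alone, 17 rose and 1 fell, and the median change was 1.54 (camera adjusted p = 5.48e-14, and adjusted p = 0.0663 with an estimated correlation). Fibroblast-like cells made up 62 of 319 mesenchymal-like cells at day 10 and 11 of 319 in healthy kidneys, and without them the median change of 19 matrix genes was 0.29, that of Tnc 1.1 ± 2.22, adjusted p = 0.936, and that of Col12a1 1.27 ± 0.29, adjusted p = 0.0943. Col1a1, a fibroblast marker, was not among these 19. Pooled fibroblast-like cells held 3614 CPM of Col1a1 in healthy kidneys (2264 to 6887 over 3 numbers) and 4599.9 CPM at day 10 (3274 to 5478 over 4 numbers). Vascular smooth muscle-like cells held 20.7 and 61.0 CPM. The fibroblast-like ranges overlap, so a rise of Col1a1 within these cells is not shown, and their larger share may account for its change. Acta2, smooth muscle actin (chromosome 19, 34240336 to 34255585), stood at 17669 ± 3110.2 against 26778 ± 3195 CPM (-0.61 ± 0.10 log2, adjusted p = 0.0114), and Myh11, the smooth muscle myosin heavy chain, changed by -0.90 ± 0.11 log2, adjusted p = 0.00343. Of 17 contractile genes, 0 rose, 8 fell and 9 did not pass. The median change was -0.56 (camera adjusted p = 2.61e-16, and adjusted p = 0.0729 with an estimated correlation), and adjusted over the list alone 1 rose and 14 fell. From healthy to day 10, vascular smooth muscle-like cells went from 191 to 146 and pericyte-like cells from 89 to 41. The contractile list was not tested apart from this change of cells, though Acta2 was also lower within vascular smooth muscle-like cells (below).

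Among other genes that changed in mesenchymal-like cells by day 10, Spp1 stood at 5719.8 ± 4404 against 10.1 ± 8.1 CPM (9.23 ± 0.47 log2, adjusted p = 1.26e-05), Itih4 rose by 6.37 ± 0.53 log2, adjusted p = 0.000392, and Timp1 by 6.89 ± 0.78. Serpina3n stood at 155 against 0.889 CPM. Other large positive changes were Nkd2 (6.44 ± 1.17), Bcl3 (5.77 ± 1.12) and Rasl10b (3.85 ± 0.43), where Nkd2 antagonises Wnt signalling. Without fibroblast-like cells the change of Nkd2 was -4.61, adjusted p = 0.471. Ren1, which encodes renin, rose from 42.5 to 272 CPM (2.66 ± 0.33 log2, adjusted p = 0.00293). Cluster 14, an unnamed mesenchymal cluster led by Ren1, held 6 of the healthy and 32 of the day 10 mesenchymal-like cells, with pooled levels of 890.3 and 1705 CPM, and vascular smooth muscle-like cells held 35.2 and 263 CPM. The largest negative changes were Pon3 (-2.83 ± 0.56), Myh6 (-2.04 ± 0.36), Baiap2l2 (-2.04 ± 0.44), Ccnd1 (-1.88 ± 0.32), Cd24a (-1.84 ± 0.22), Cbfa2t3 (-1.8 ± 0.39), Nhsl2 (-1.62 ± 0.33) and Aspn (-1.61 ± 0.26). Of 18 Wnt signalling genes, 1 rose, 0 fell and 17 did not pass. When adjusted over the list alone, 9 rose and 0 fell. Its median change was 2.56 (camera adjusted p = 9.60e-07, and adjusted p = 0.0729 with an estimated correlation). The Wnt list was not tested without fibroblast-like cells. Its member Nkd2 stood at 717 CPM in pooled day 10 fibroblast-like cells, 0.060 CPM in vascular smooth muscle-like and 0.075 CPM in pericyte-like cells. Of 19 oxidative phosphorylation genes, 0 rose, 5 fell and 14 did not pass. Adjusted over the list alone, 0 rose and 11 fell, and the median change was -0.46 (camera adjusted p = 5.19e-12, and adjusted p = 0.112 with an estimated correlation), with Atp5b at -0.71 ± 0.10 and Cox5a at -0.77 ± 0.14. Pdgfrb did not pass (-0.070 ± 0.12 log2, adjusted p = 0.868). In all, 252 genes passed, 139 higher and 113 lower at day 10, and every gene named as passing had 1 sign in 4 of 4 numbers. Of the 31 lists, 15 passed camera with its preset correlation, 11 higher and 4 lower, and 0 did with an estimated correlation, where 12 had an unadjusted p under 0.05. The count of genes was 113 without the block, 69 without number 1, 53 without number 4, 40, 133 and 136 without plates 4, 2 and 5 in turn, and 103 without fibroblast-like cells.

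**Figure D1:**
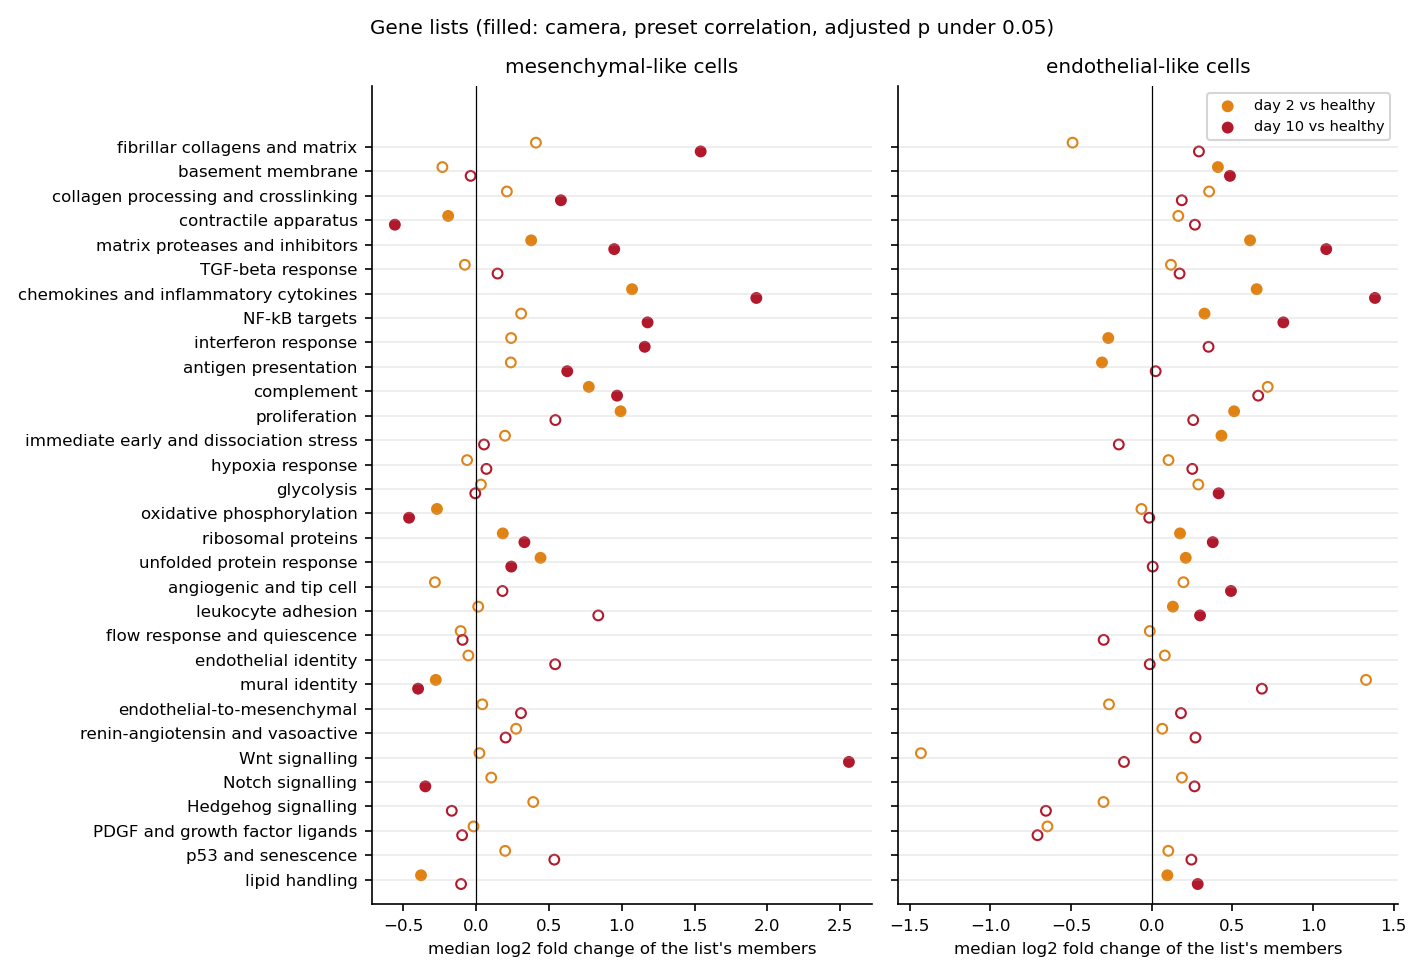
Median log2 fold change of the tested members of 31 gene lists (horizontal axis) in mesenchymal-like and endothelial-like cells at day 2 and day 10 of UUO against healthy cells, with filled circles where camera with its preset correlation gave an adjusted p under 0.05. The fibrillar collagen and matrix list sits at 1.54 and the contractile list at -0.56 in mesenchymal-like cells at day 10.

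Comparing day 10 with day 2 in mesenchymal-like cells asks what changes as obstruction persists. Spp1 was higher at day 10 by 3.01 ± 0.35 log2, adjusted p = 0.0108, and without fibroblast-like cells its change was -3.34. The mitochondrial carrier gene Ucp2 rose by 3.0 ± 0.42, Lgals9, which encodes galectin 9, by 2.44 ± 0.31, and Ppic by 1.86 ± 0.17. Ccdc80, which was lower at day 2 than in healthy kidneys, was higher at day 10 than at day 2 by 1.87 ± 0.20 log2, adjusted p = 0.00713. Kap, outside the rule for named genes and chosen after its values were seen, was the third gene lower at day 10 (-4.98 ± 0.56 log2, adjusted p = 0.00996). The epoxide hydrolase gene Ephx3 (-2.05 ± 0.22) and the olfactory receptor gene Olfr558 (-0.93 ± 0.12) were the others. In all, 9 genes passed, 6 higher and 3 lower, and each gene named had 1 sign in 4 of 4 numbers. Of 25 fibrillar collagen and matrix genes, 0 rose, 0 fell and 25 did not pass. With p adjusted over the list alone, 11 rose and 0 fell, and the median change was 1.43 (camera adjusted p = 5.70e-22, and adjusted p = 0.0663 with an estimated correlation). Camera with its preset correlation passed 15 of 31 lists, 9 higher and 6 lower, and with an estimated correlation 0, with 7 at an unadjusted p under 0.05. The count of genes was 3 without the block, 2 without number 1, 4 without number 4 and 1 without fibroblast-like cells. Without plate 4, edgeR passed 0 genes, with 949 at an unadjusted p under 0.05.

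Mesenchymal subclasses differed in where these transcripts were found. In fibroblast-like cells, pooled over numbers because 11 healthy and 13 day 2 cells were too few to test, Spp1 stood at 9.44, 13428 and 32320 CPM in healthy, day 2 and day 10 cells, and Timp1 at 41.3, 2601 and 1641 CPM. Dcn, the proteoglycan decorin, stood at 13893, 5788 and 1649 CPM there, and Col1a1 at 3614, 3715 and 4599.9 CPM. Tnc stood at 0, 1397 and 1629 CPM and Col12a1 at 63.5, 200.4 and 2910.5 CPM in the same cells. These pooled values vary widely between numbers and cells. The healthy cells numbered 1, 0, 2 and 8 in numbers 1 to 4, so the healthy level rests mostly on number 4. Over the 3 numbers with healthy cells, Timp1 ranged from 0 to 247 CPM and Dcn from 11743 to 22917 CPM. Over the 3 numbers with fibroblast-like cells at day 2, Spp1 ranged from 1061 to 39460 CPM, Timp1 from 697 to 3622 CPM and Dcn from 104 to 8994 CPM, and at day 10 Spp1 ranged over 4 numbers from 12729 to 52661 CPM. The median cell held 605 CPM of Spp1 at day 2 and 4537 CPM at day 10. Pooled Itih4 at day 2 and day 10 stood at 1606 and 1946 CPM in vascular smooth muscle-like cells. It stood at 30.8 and 49.5 CPM in pericyte-like cells and at 1.61 and 3.37 CPM in fibroblast-like cells. In vascular smooth muscle-like cells, Itih4 rose by 6.39 ± 0.59 log2, adjusted p = 0.000536 at day 2 and by 6.62 ± 0.60 log2, adjusted p = 0.000591 at day 10, and Serpina3n stood at 315 against 0.0219 CPM at day 2. Osmr rose by 3.22 ± 0.32 and 3.03 ± 0.31, and Crispld2, a secreted glycoprotein gene, by 2.85 ± 0.37 and 3.88 ± 0.39. Spp1 rose by 5.46 ± 0.65 at day 2, to a pooled level of 383.6 CPM that was 16.5 CPM at day 10. At day 2 the endothelial subclasses held from 319 to 1032 CPM of Spp1, and Havcr1 stood at 5.59 CPM in mesenchymal-like cells. Esr1, the oestrogen receptor alpha gene, rose by 3.72 ± 0.63 at day 10, and Acta2 changed by -0.36 ± 0.067 log2, adjusted p = 0.0334 at day 2 and -0.48 ± 0.067 log2, adjusted p = 0.0071 at day 10. Ccdc80 (-2.07 ± 0.24), Prkcd (-1.95 ± 0.29) and Ogn (-1.83 ± 0.31) were lower at day 2, and Adcy5 (-1.61 ± 0.18) at day 10. Gpx3, a secreted glutathione peroxidase that the proximal tubule makes in quantity, was lower at day 10 by -5.98 ± 0.65 log2, adjusted p = 0.00137, in cells where Kap went from 115 to 0.206 CPM. Pooled Gpx3 in these cells stood at 141, 266 and 1.96 CPM in healthy, day 2 and day 10 kidneys. The changes given for vascular smooth muscle-like cells had 1 sign in 4 of 4 numbers. Cluster 9 held 148 of the healthy vascular smooth muscle-like cells, and cluster 11 held 121 of those at day 2 and 118 of those at day 10.

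In vascular smooth muscle-like cells 124 of 11979 genes passed at day 2 (80 higher, 44 lower) and 113 at day 10 (69 higher, 44 lower). Only Gpx3 passed between day 10 and day 2 (-7.25 ± 0.69 log2, adjusted p = 0.00744, lower in 4 of 4 numbers). In pericyte-like cells edgeR passed 0 of 10359 genes at day 2, with 411 at an unadjusted p under 0.05, and Acta2 had a value of 0.44 ± 0.20 log2, adjusted p = 0.999. These 411 are fewer than a share of 0.05 of the genes tested, so they show no excess over no change. Without number 1 the smooth muscle counts were 48 and 61, without number 4 40 and 33, without plate 2 68 and 63, and without plate 4 39 and 38, while leaving out plate 3 gave 71 at day 2.

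**Figure D2:**
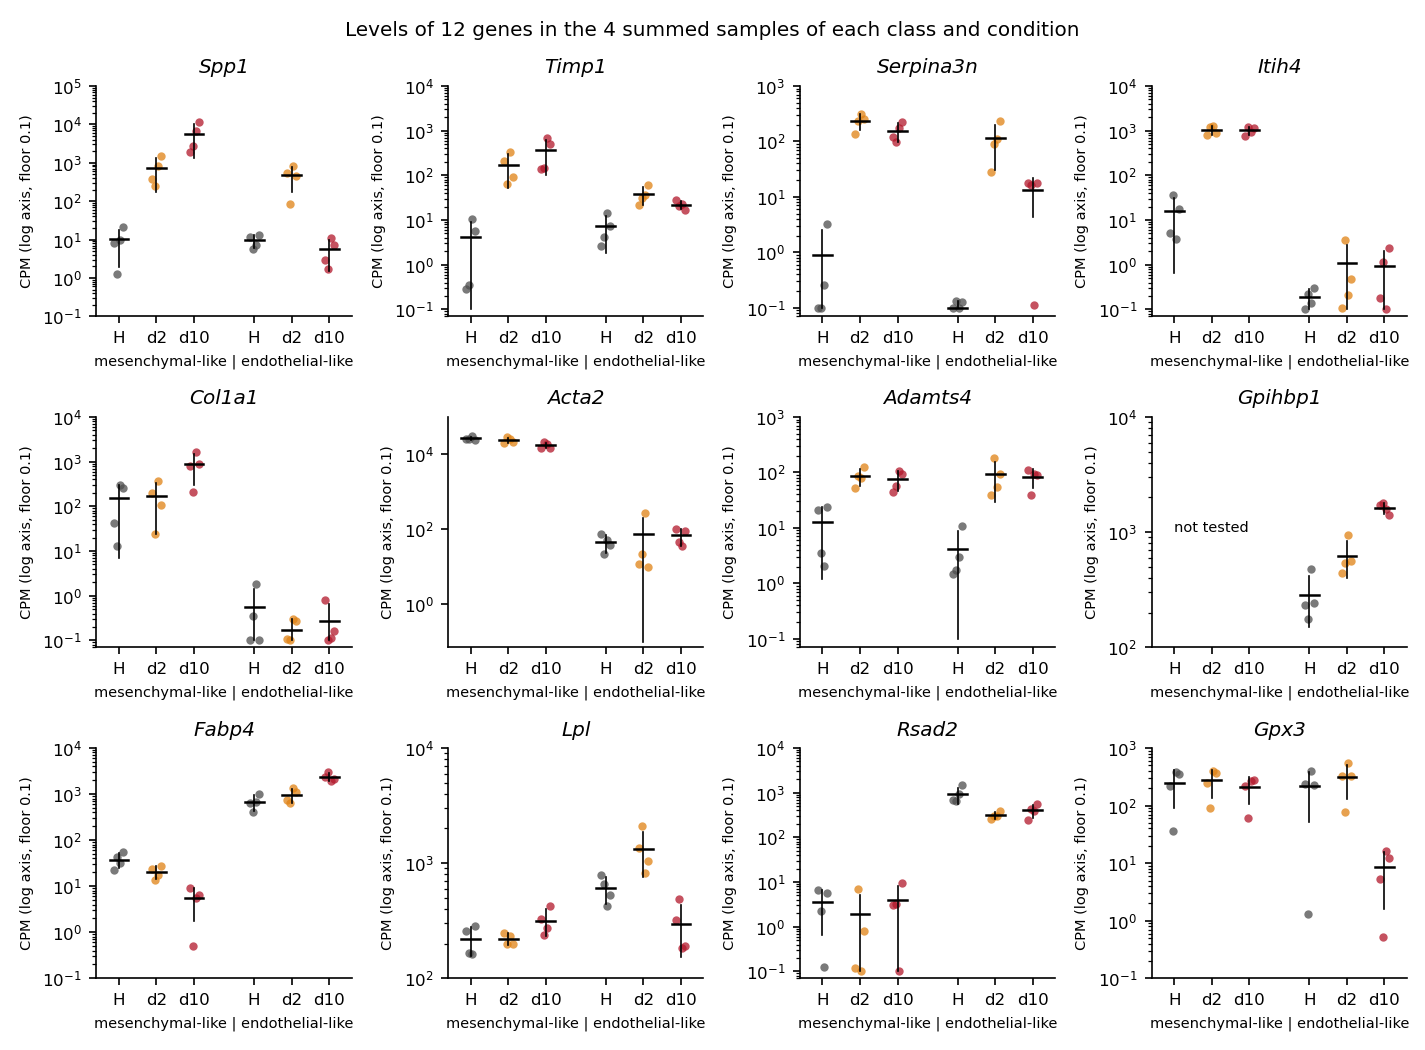
CPM (log axis) of 12 genes in each of the 4 sums per class and condition (points; H healthy, d2 and d10 days of UUO), with the mean (bar) and 1 SD either side (line), where values under 0.1 are drawn at 0.1. Spp1 averages 5719.8 CPM in day 10 mesenchymal-like cells and 5.68 CPM in day 10 endothelial-like cells.

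Comparing endothelial cells at day 2 with healthy endothelium asks how these cells respond early to obstruction. Lrg1, a secreted leucine-rich glycoprotein, rose from 32.6 to 397 CPM (3.62 ± 0.51 log2, adjusted p = 0.0201), and Adamts4, a protease of matrix proteoglycans, by 4.69 ± 0.73 log2, adjusted p = 0.034. Spp1 stood at 469.7 ± 297 against 9.58 ± 3.63 CPM (5.27 ± 0.49 log2, adjusted p = 0.00594), in cells where Havcr1 went from 0 to 9.16 CPM. The other largest positive changes were Tnfaip8l1 (2.54 ± 0.30), Tmem173 (2.31 ± 0.37), Serpine2 (2.28 ± 0.30), Gda (2.07 ± 0.28) and Abca1 (1.96 ± 0.27), of which Abca1 exports cholesterol and Tmem173 encodes the DNA-sensing adaptor STING. Lpl, lipoprotein lipase, rose by 1.06 ± 0.17, and Col4a2, a chain of basement membrane collagen, by 1.12 ± 0.17. Tgfb2, a ligand of the transforming growth factor beta family, changed by -2.35 ± 0.23 log2, adjusted p = 0.00594, and the interferon-induced genes Cmpk2 and Rsad2 changed by -1.78 ± 0.22 and -1.51 ± 0.17. Gas6 (-1.17 ± 0.17) and Tinagl1 (-1.11 ± 0.16) were the other genes lower at day 2 that are named. Pecam1 did not pass (-0.026 ± 0.11 log2, adjusted p = 0.987). Of 23 interferon response genes, 0 rose, 1 fell and 22 did not pass. The median change was -0.27 (camera adjusted p = 0.00168, and adjusted p = 0.435 with an estimated correlation), and adjusted over the list alone 0 rose and 2 fell. Of 17 basement membrane genes, 1 rose, 0 fell and 16 did not pass. When adjusted over the list alone, 4 rose and 1 fell. Its median change was 0.41 (camera adjusted p = 0.0166, and adjusted p = 0.388 with an estimated correlation). In all, 28 of 13398 genes passed, 22 higher and 6 lower, and the passing genes named had 1 sign in 4 of 4 numbers. A fit to the healthy and day 2 sums alone, without those of day 10, passed 3 genes. Camera passed 12 of 31 lists, 10 higher and 2 lower, and with an estimated correlation 0, with 4 at an unadjusted p under 0.05. The count of genes was 3 without number 1, 4 without plate 4, and 16, 14 and 16 without plates 1, 2 and 3 in turn, and edgeR passed 0 genes without number 4, where 856 had an unadjusted p under 0.05.

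At day 10, the comparison with healthy endothelium asks which endothelial changes go with later obstruction. Gpihbp1, which anchors lipoprotein lipase to the capillary wall (chromosome 15, 75596630 to 75598213), stood at 1620.4 ± 170.3 against 283 ± 134 CPM (2.63 ± 0.24 log2, adjusted p = 0.00169). Fabp4, a fatty acid-binding protein, rose by 1.85 ± 0.28 and Scarb1, the receptor for high-density lipoprotein, by 1.49 ± 0.24, whereas Lpl was lower by -1.13 ± 0.17 log2, adjusted p = 0.019. Of 15 lipid-handling genes, 3 rose, 1 fell and 11 did not pass. Adjusted over the list alone, 6 rose and 1 fell, and the median change was 0.28 (camera adjusted p = 0.0262, and adjusted p = 0.417 with an estimated correlation). Dll4, a Notch ligand of endothelial tip cells, rose by 1.3 ± 0.18 log2, adjusted p = 0.0127, Mcam by 0.95 ± 0.17 and Trp53i11 by 3.01 ± 0.57. Of 25 angiogenic and tip cell genes, 3 rose, 0 fell and 22 did not pass. With p adjusted over the list alone, 9 rose and 2 fell, and the median change was 0.49 (camera adjusted p = 0.0116, and adjusted p = 0.388 with an estimated correlation). Col4a1 and Col4a2 rose by 1.17 ± 0.20 and 1.2 ± 0.17, and Cx3cl1, a membrane-bound chemokine, by 1.38 ± 0.20. Cluster 8, led by Apln, Esm1 and Cxcr4, held 182 of 356 endothelial-like cells at day 10 and 8 of 352 in healthy kidneys, and peritubular capillary-like cells numbered 23 and 64, so the endothelial changes at day 10 go with a change of clusters.

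The largest positive day 10 changes were Adamts4 (4.71 ± 0.73), Serpina3g (3.15 ± 0.61), Tnfaip8l1 (2.99 ± 0.30), Gda (2.9 ± 0.29), Tubb6 (2.84 ± 0.41) and Uchl1 (2.41 ± 0.29). Gpx3 had the most negative change, at 8.67 ± 7.06 against 216 ± 165 CPM (-4.41 ± 0.77 log2, adjusted p = 0.0321), in cells where Kap went from 167 to 2.46 CPM. At day 2 the mean of Kap was lower than in healthy cells (37.9 ± 43 CPM), whereas that of Gpx3 was not (324 ± 197 CPM). The other largest negative changes were Calca (-3.58 ± 0.69), Fam107a (-2.8 ± 0.50), Thrsp (-2.39 ± 0.38), Magix (-2.09 ± 0.38), Amigo2 (-2.05 ± 0.26), Klf12 (-1.96 ± 0.32) and Fgfr3 (-1.83 ± 0.30), and Rsad2 and Tgfb2 were lower by -1.16 ± 0.17 and -1.75 ± 0.23. In all, 90 endothelial genes passed, 45 higher and 45 lower, and those named had 1 sign in 4 of 4 numbers. A fit to the healthy and day 10 sums alone, without those of day 2, passed 1 gene. Camera passed 9 of 31 lists, all higher, and with an estimated correlation 0, with 3 at an unadjusted p under 0.05. The count of genes was 42 without the block, 11 without number 1, 6 without number 4, 39 without plate 2 and 15 without plate 4.

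Between day 10 and day 2, Spp1 was lower in endothelial-like cells at day 10 by -6.33 ± 0.51 log2, adjusted p = 0.00080, and Lpl by -2.19 ± 0.18 log2, adjusted p = 0.00080, each in 4 of 4 numbers. They were among 3 genes that passed, all lower at day 10. The other was Tmem27, a gene of kidney tubule cells that fell outside the rule for named genes and was chosen after its values were seen (-9.7 ± 1.17 log2, adjusted p = 0.0252). Of 23 interferon response genes, 0 rose, 0 fell and 23 did not pass. The median change was 0.49 (camera adjusted p = 1.44e-09, and adjusted p = 0.388 with an estimated correlation), and adjusted over the list alone 6 rose and 0 fell. Camera passed 5 of 31 lists, 4 higher and 1 lower, and with an estimated correlation 0, with 2 at an unadjusted p under 0.05. The count of genes was 1 without plate 4, 5 without plate 3 and 7 without plate 6, and edgeR passed 0 without number 4, where 675 genes had an unadjusted p under 0.05.

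Endothelial cells with glomerular markers were tested as a group of their own, made of cluster 4, which held 118 of the healthy cells, cluster 3, which held 154 of those at day 2, and cluster 8, which held 182 of the 255 at day 10. Cluster 8 met the most markers for glomerular endothelium but stayed unnamed by the naming rule, since its 10 leading genes hold Esm1, a peritubular capillary marker, and no glomerular one. The day 10 tests therefore compare mostly cluster 8 with mostly cluster 4, and the type of cluster 8 is open. Esm1, a secreted proteoglycan of angiogenic endothelium, stood at 2183 ± 575 against 142 ± 143 CPM at day 10 (4.39 ± 0.63 log2, adjusted p = 0.0101), and Fabp4 rose by 3.7 ± 0.44 log2, adjusted p = 0.00401. Gja1 (3.27 ± 0.58), Cldn5 (3.13 ± 0.52) and Rnd1 (2.95 ± 0.39) also rose, Gja1 encoding the gap junction protein connexin 43 and Cldn5 a tight junction claudin. Genes lower at day 10 included Atp13a3 (-3.08 ± 0.29), Fgfr3 (-2.86 ± 0.37), Clec14a (-2.3 ± 0.22), Slc6a6 (-2.06 ± 0.25) and Sdpr (-1.89 ± 0.14). At day 2, Tnfaip8l1 (2.83 ± 0.43), Emilin1 (1.76 ± 0.20), Slco2a1 (1.2 ± 0.18) and Lifr (1.01 ± 0.14) were higher and Cmpk2 (-2.09 ± 0.31), Ltbp4 (-1.92 ± 0.26), Rsad2 (-1.56 ± 0.23), Tinagl1 (-1.52 ± 0.24) and Sdpr (-1.01 ± 0.13) were lower. Between day 10 and day 2, Ifit1 (3.42 ± 0.49), Gpihbp1 (2.03 ± 0.17) and B2m (0.71 ± 0.10) were higher at day 10 and Spp1 (-5.92 ± 0.90), Lpl (-2.58 ± 0.18), Slco2a1 (-1.85 ± 0.18), Pi16 (-1.28 ± 0.14) and Klf2 (-1.13 ± 0.15) were lower, of which Klf2 is a transcription factor induced by blood flow. The named genes had 1 sign in 4 of 4 numbers. Of 12030 genes tested, 17 passed at day 2 (12 higher, 5 lower), 94 at day 10 (42 higher, 52 lower) and 23 between the days (8 higher, 15 lower). Without the block on number these counts were 25, 82 and 24. Without number 1 they were 1, 20 and 2, and without number 4 0 (edgeR, with 723 at an unadjusted p under 0.05), 14 and 2. Without plate 3 they were 0 (849 at an unadjusted p under 0.05), 49 and 8, without plate 4 1, 54 and 5, and without plate 6 0 (869 at an unadjusted p under 0.05), 54 and 10. Leaving out plate 1 gave 4 at day 2 and 14 between the days, plate 5 2 at day 2 and plate 2 14 between the days.

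In arterial-like endothelium, tested in 3 or 4 sums per condition and chosen after the data were seen, edgeR passed 4 of 11594 genes at day 10 (3 higher, 1 lower). Ednrb, a receptor of endothelin, was higher by 3.61 ± 0.37 log2, adjusted p = 0.0341, Litaf by 2.1 ± 0.22 and Jam2, a junctional adhesion molecule, by 1.7 ± 0.20. Gpx3 was lower by -4.44 ± 0.50 log2, adjusted p = 0.0341, in cells where the pooled level of Kap went from 244 to 2.29 CPM. At day 2 and between the days edgeR passed 0 and 0 genes, with 579 and 422 at an unadjusted p under 0.05. In peritubular capillary-like cells it passed 0 of 10135 at day 2, with 373 at an unadjusted p under 0.05. The counts of 579, 422 and 373 do not exceed a share of 0.05 of the genes tested, so they show no excess over no change. The arterial day 10 count was 2 without the block and 2 without plate 5, and edgeR passed 0 without number 1, number 4, or plate 1, 2 or 4 (506, 372, 608, 506 and 471 at an unadjusted p under 0.05).

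Tests of the difference between the classes ask whether mesenchymal and endothelial cells respond differently to obstruction. Spp1 had the largest difference, with a day 10 change that was 10.4 ± 0.78 log2 units higher in mesenchymal-like than in endothelial-like cells (adjusted p = 6.49e-07). Timp1 (4.62 ± 0.94), Gpx3 (4.56 ± 0.88), the semaphorin gene Sema6a (4.02 ± 0.50) and Cpne8 (3.65 ± 0.41) also changed more positively in mesenchymal-like cells at day 10, and Fabp4 (-4.82 ± 0.69), Rnd1 (-4.0 ± 0.81), Kti12 (-2.81 ± 0.57), Hmbox1 (-2.8 ± 0.57) and Taf7 (-2.33 ± 0.48) more positively in endothelial-like cells. The pooled level of Gpx3 went from 1964 to 1056 CPM in fibroblast-like cells (11 healthy and 62 day 10 cells) and from 141 to 1.96 CPM in vascular smooth muscle-like cells, while Kap went from 129 to 0.833 CPM in mesenchymal-like and from 167 to 2.46 CPM in endothelial-like cells. At day 2, the positive differences were Sema6a (2.91 ± 0.49), Ltbp1 (2.28 ± 0.40), Clu (2.13 ± 0.36), Elovl1 (1.29 ± 0.19) and Sncg (1.23 ± 0.19). The 1 negative difference was 4631405J19Rik (-3.05 ± 0.45 log2, adjusted p = 0.0122), outside the rule for named genes and chosen after its values were seen. In all, 6 genes passed at day 2 (5 higher, 1 lower in mesenchymal-like cells) and 47 at day 10 (30 higher, 17 lower), of 15412 tested. At day 10 the fibrillar collagen list changed more positively in mesenchymal-like cells (adjusted p = 0.00467, and adjusted p = 0.541 with an estimated correlation), and the contractile list more negatively (adjusted p = 0.00393, and 0.541 with an estimated correlation). The day 2 and day 10 counts were 2 and 26 without the block, 1 and 10 without number 1 and 3 and 7 without plate 4, and at day 10 19 without plate 2, 20 without plate 5 and 8 without fibroblast-like cells. With each mouse as its own block edgeR passed 0 genes at day 2 (810 at an unadjusted p under 0.05) and 3 at day 10, and without number 4 0 (1148 at an unadjusted p under 0.05) and 3.

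The day 2 and day 10 changes shared genes within each class. In mesenchymal-like cells 50 genes were higher and 10 were lower at both days, and 0 passed in opposite directions in edgeR. In endothelial-like cells 10 genes were higher and 6 were lower at both days, and Lpl alone passed in opposite directions. Independent lists of these lengths would share 0.687 and 0.148 genes in mesenchymal-like and 0.0739 and 0.0202 in endothelial-like cells, which leaves out that both comparisons use the same healthy sums. In 20 data sets simulated with the same healthy sums in both comparisons and no injury effect, edgeR found a mean of 0 genes higher and 0.050 lower at both days in mesenchymal-like cells and 0 of either in endothelial-like cells. So few genes passed there (a mean of 0.25 at day 2 and 0.15 at day 10 in mesenchymal-like cells) that an overlap could hardly arise, so the part of the shared healthy sums in the observed overlaps is not known. That sharing also correlates the changes. Across 7827 mesenchymal genes, which are not independent replicates, Pearson's r of the log2 changes was 0.667 against 0.498 ± 0.0099 (SD) in data simulated with no injury effect, and across 7501 endothelial genes 0.648 against 0.501. The covariance was 0.197 against 0.0768 simulated in mesenchymal-like cells and 0.168 against 0.081 in endothelial-like cells. The 4 numbers were also split, with day 2 read in some and day 10 in the others, each against its own healthy sums. There r averaged 0.272 (0.242 to 0.295) and 0.207 (0.155 to 0.239), and the covariance 0.13 and 0.0909. Each change then rests on fewer numbers and on plain differences of log2 CPM, which adds noise. The lower r therefore cannot be put down to the separate healthy sums alone.

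Cell shares within each gate ask which populations the sorted cells came from, and they describe the cells that were sorted, not their abundance in the kidney. Fibroblast-like cells made up 16.1% ± 8.71 against 2.67% ± 2.94 of the mesenchyme gate at day 10 and in healthy kidneys (SD, n = 4), a difference of 13.4 ± 6.81 points. Mesangial-like cells made up 9.13% ± 5.62 against 5.18% ± 5.8 and pericyte-like cells 10.6% ± 2.12 against 26.3% ± 8.03. In the endothelia gate, glomerular-marker cells made up 67.8% ± 15.1 against 46.5% ± 17.1 and peritubular capillary-like cells 5.52% ± 5.84 against 16% ± 11.2, and both differences rest on counting cluster 8 (182 of the 255 glomerular-marker cells at day 10) with the glomerular-marker clusters. Each of these 5 differences had 1 sign in 4 of 4 numbers, with a two-sided exact sign-flip p of 0.125, the smallest that 4 numbers allow, so that none could reach 0.05, and an adjusted p of 0.433 over 45 tests. In edgeR tests of cell numbers, fibroblast-like cells were higher at day 10 (log2 change 2.42, adjusted p = 0.000109), and pericyte-like cells (log2 change -1.17, adjusted p = 0.00409) and peritubular capillary-like cells (log2 change -1.53, adjusted p = 0.0194) were lower, while mesangial-like cells (log2 change 0.75, adjusted p = 0.213) and glomerular-marker cells (log2 change 0.56, adjusted p = 0.201) did not pass. When cells needed 2000 genes, the day 10 differences of glomerular-marker and peritubular capillary-like cells were -5.56 and 16.3 points, and at a clustering resolution of 1.5 that of peritubular capillary-like cells was 5.86 points.

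**Figure D3:**
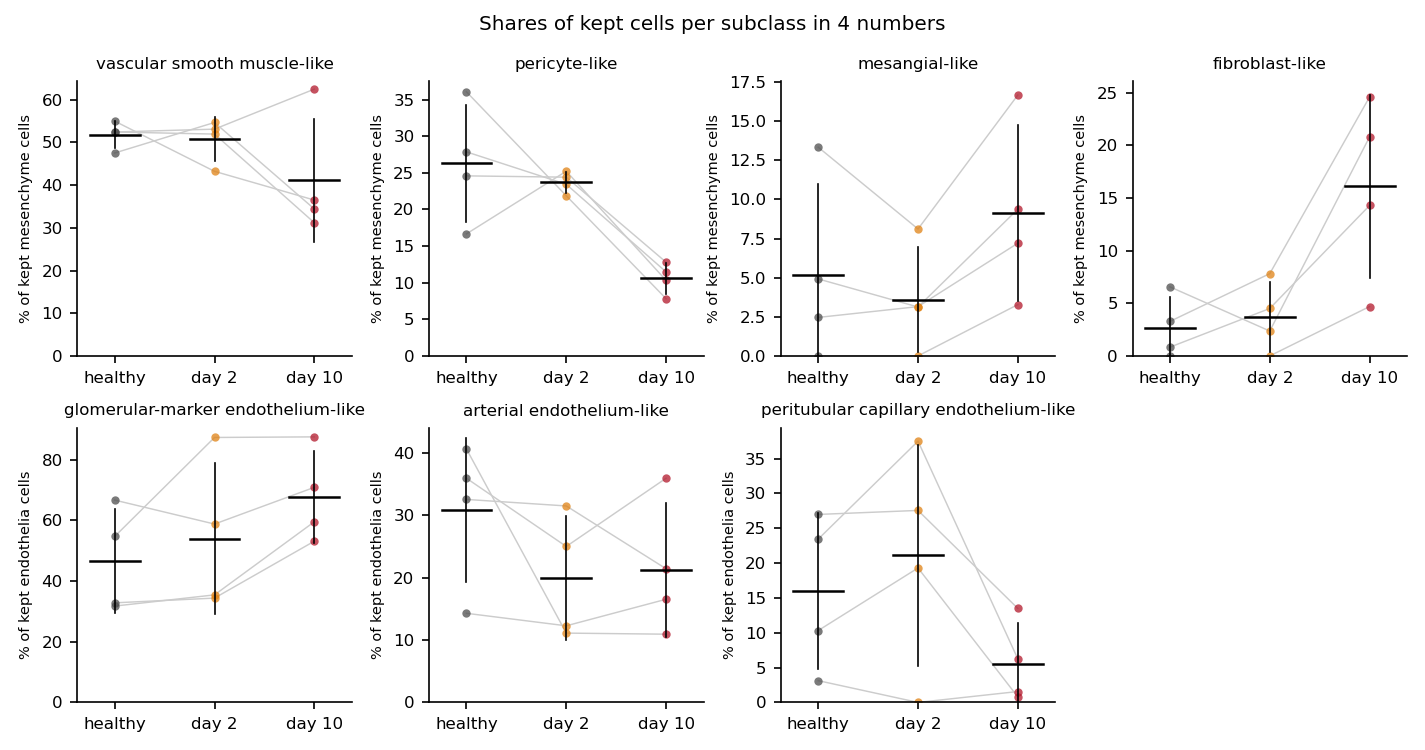
Share of the kept cells of a gate, in percent, that each of 7 named subclasses made up in the 4 numbers (points; grey lines join a number across conditions), with the mean (bar) and 1 SD either side (line). Fibroblast-like cells average 16.1% of the mesenchyme gate at day 10, and pericyte-like cells 10.6%.

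Cells with a proliferation signature, at least 3 of 10 cell cycle genes detected, were few at every time. They numbered 0 of 319 healthy (which allows a share of up to 0.94%), 2 of 316 day 2 and 4 of 319 day 10 mesenchymal-like cells, and 2 of 352, 3 of 347 and 5 of 356 endothelial-like cells. The differences from healthy had exact sign-flip p of 0.5 in both classes at both days (adjusted p = 0.6 over 6 tests), and 2 of 4 numbers were higher in each. Reads on genes relative to reads on the added ERCC spike-in RNA, an index of RNA per well, differed from healthy by 0.36 ± 0.11 log2 units at day 2 and 0.27 ± 0.26 at day 10 in mesenchymal-like cells, and by 0.32 ± 0.20 and 0.21 ± 0.20 in endothelial-like cells (SD of the paired difference, n = 4), each higher in 4 of 4 numbers with an exact sign-flip p of 0.125 (adjusted p = 0.188 over 6 tests). The index holds only if every well received the same amount of spike-in, which was not tested. Each condition and gate filled the same plate columns on every plate. A difference in spike-in between columns therefore cannot be told apart from a difference in RNA.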

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

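The tests of technical explanations for 3 patterns below (tubule RNA, matrix genes and plate rows C and D of plate 1) were chosen after the patterns were seen, and the splits of the samples were planned, apart from those of arterial-like and peritubular capillary-like cells. A group of 4 values was checked for a value far from the others by Dixon's criterion. It picked 31 of 332 groups, a number that is not set against chance, because in 10 of them the other 3 values were 0, where any value above 0 meets the criterion.

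In mesenchymal-like cells the values far from the other numbers were Baiap2l2 at 4.15 CPM at day 10 in number 4 (others 13.4 to 14.8), Grb14 at 233 CPM in healthy kidneys in number 2 (others 265 to 271) and Grb14 at 67.7 CPM at day 2 in number 1 (others 129 to 138). These were followed by Lgals9 at 69.8 CPM at day 2 in number 1 (others 21.5 to 27.6), Ntrk3 at 122 CPM at day 2 in number 2 (others 57.9 to 59.8) and Serpina3n at 3.3 CPM in healthy kidneys in number 4 (others 0 to 0.253). Further such values were Tnc at 25 CPM in healthy kidneys in number 1 (others 0.0509 to 4.05), Havcr1 at 0.0258 CPM in healthy kidneys in number 4 (others 0) and Havcr1 at 1.05 CPM at day 10 in number 3 (others 0 to 0.0965). In endothelial-like cells they were Adamts4 at 10.8 CPM in healthy kidneys in number 4 (others 1.46 to 2.94), Col4a2 at 1215 CPM at day 2 in number 3 (others 679 to 754) and Cx3cl1 at 212 CPM in healthy kidneys in number 4 (others 544 to 569). These were followed by Fam107a at 206 CPM in healthy kidneys in number 2 (others 43.5 to 58.8), Tmem27 at 0.0599 CPM at day 10 in number 4 (others 0) and Tubb6 at 476 CPM at day 10 in number 1 (others 104 to 156). Further such values were Acta2 at 265 CPM at day 2 in number 3 (others 10.0 to 21.2), Col1a1 at 1.8 CPM in healthy kidneys in number 3 (others 0.0503 to 0.347) and Pdgfrb at 40.5 CPM at day 2 in number 3 (others 0.378 to 2.02). In vascular smooth muscle-like cells they were Gpx3 at 130.5 CPM at day 2 in number 2 (others 279 to 309) and Serpina3n at 0.0877 CPM in healthy kidneys in number 4 (others 0). In glomerular-marker cells they were Slco2a1 at 1706 CPM at day 2 in number 4 (others 1477 to 1503). Among shares of the mesenchyme gate, such values were distal nephron and collecting duct-like cells at 0.901% at day 2 in number 1 (others 0), proximal tubule-like cells at 0.80% at day 10 in number 4 (others 0) and proximal tubule-like cells at 1.56% at day 2 in number 3 (others 0). These were followed by vascular smooth muscle-like cells at 62.5% at day 10 in number 2 (others 31.2 to 36.5). Among shares of the endothelia gate, they were distal nephron and collecting duct-like cells at 0.794% at day 10 in number 4 (others 0), distal nephron and collecting duct-like cells at 0.787% at day 2 in number 4 (others 0) and podocyte-like cells at 6.3% at day 10 in number 1 (others 0). These were followed by podocyte-like cells at 0.794% in healthy kidneys in number 4 (others 0). The share with a proliferation signature stood apart for mesenchymal-like cells at 5.88% at day 10 in number 3 (others 0 to 0.99). The log2 ratio of gene reads to ERCC reads stood apart for endothelial-like cells at 8.57 at day 2 in number 2 (others 8.08 to 8.13).

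The injury effect differed between classes for 6 genes at day 2 and 47 at day 10 by the interaction test, with the report's values as mesenchymal minus endothelial log2 change. At day 2, with 5 higher and 1 lower, these were 2.91 for Sema6a, 2.28 for Ltbp1, 2.13 for Clu, 1.29 for Elovl1, 1.23 for Sncg and -3.05 for 4631405J19Rik. At day 10 they were 10.4 for Spp1, 4.62 for Timp1, 4.56 for Gpx3, 4.02 for Sema6a, 3.65 for Cpne8, -4.82 for Fabp4, -4.0 for Rnd1, -2.81 for Kti12, -2.8 for Hmbox1 and -2.33 for Taf7. Both classes of a condition and number come from the same mouse, and with the mouse as block edgeR passed 0 genes at day 2 (810 at an unadjusted p under 0.05) and 3 at day 10, and 13 of these 16 genes no longer passed. Signal outside the comparisons was seen in the control wells, of which the highest held 30393 reads on genes, and in the entry named eGFP, which the labels do not explain and which stood at 569.9, 616 and 515 CPM in healthy, day 2 and day 10 mesenchymal-like cells, against 4.45, 9.08 and 4.99 CPM in endothelial-like cells.

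Transcripts of the proximal tubule were found in sorted mesenchymal-like and endothelial-like cells, and Kap was lower at day 10, whereas Gpx3 in mesenchymal-like cells was at 249, 272 and 211 CPM (pooled fibroblast-like cells went from 1964 to 1056 CPM, from 11 to 62 cells), and Cubn was at 3.06 CPM in healthy and 6.26 CPM in day 10 mesenchymal-like cells. Over 6 tubule markers the log2 ratio of the mesenchymal-like to the endothelial-like healthy level ranged from -0.69 to 1.11 (median -0.18), highest for Gpx3, which fibroblast-like cells held before injury, so whether free RNA of tubule cells in the wells gave all of them stays open, but 75.5% or more of the healthy cells of each class had a read of Kap, which whole tubule cells or doublets among a few wells would not give. Spp1 at day 2 had a mean log2 ratio of 0.69 between the classes, under the limit of 1 set for a shared source but with an SD of 1.15, so free RNA may account for part of its day 2 rise. However, pooled fibroblast-like cells held 13428 CPM at day 2 (13 cells, 1061 to 39460 CPM over 3 numbers) against 383.6 CPM in vascular smooth muscle-like and 337 CPM in pericyte-like cells, so the ratio of the classes hides a difference between subclasses that rests on few cells, and how much of the mesenchymal rise each source gave stays open. At day 10 the Spp1 ratio was 9.64, which free RNA in all wells would not give, and pooled fibroblast-like cells held 32320 CPM against 16.5 CPM in vascular smooth muscle-like cells.

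The fibrillar collagen and matrix list had a higher median in mesenchymal-like cells at day 10, when fibroblast-like cells were more numerous, and without these cells the median change of 19 list members outside the fibroblast and mesenchymal markers was 0.29 (bootstrap interval -0.10 to 1.10), against 1.54 with them, and 0 rather than 9 of them rose in edgeR (7 of the 19 at an unadjusted p under 0.05). The bootstrap drew list members and not mice, so its interval gives the spread over genes and not the error between mice. The interval holds both 0 and 0.77, the value midway between 0 and the median with them. Whether a larger share of fibroblast-like cells accounts for most of the change therefore stays open. The interval lies under 1.54, but single members had wide SEs without these cells, such as Tnc (1.10 ± 2.22), Vcan (0.33 ± 2.03) and Col5a3 (6.06 ± 2.70). Fn1, Postn, Tnc, Col12a1 and Col8a1 among them are myofibroblast markers. The other 14 had a median of 0.27 without fibroblast-like cells (interval over genes -0.10 to 0.43, under the midway value of 0.70) against 1.39 with them. A larger share of fibroblast-like cells, higher levels within them, or both may account for most of the change of these 14. The test was first run on 23 members, with a median of 0.25, of which 12 rose with and 0 without fibroblast-like cells, then on the 19 and last on the 14. Levels within pooled fibroblast-like cells went both ways from healthy kidneys to day 10 (11 and 62 cells). They went from 63.5 to 2910.5 CPM for Col12a1, 0 to 1629 for Tnc, 13893 to 1649 for Dcn and 1381 to 286 for Lum. Col1a1 stood at 3614 and 4599.9 CPM, with ranges over numbers that overlap (2264 to 6887 and 3274 to 5478 CPM). Healthy Lum ranged from 7.89 to 5598 CPM over 3 numbers, with a median cell of 7.89 CPM, so its fall rests on few cells. Among the 14 members, levels in these cells were looked up only for Col5a2 (172 to 1216 CPM) and Thbs2 (19.6 to 512 CPM). Those of the other members were not examined there, so these values do not stand for the set. The test does not separate such changes within fibroblast-like cells from a larger share. Free RNA in the wells is excluded for Col1a1, whose log2 ratio of mesenchymal-like over endothelial-like cells at day 10 was 9.17.

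Wells of rows C and D of plate 1 carried reads of genes foreign to the sort, such as Ambn and S100a8, and cluster 12 took 36 of its 41 cells from them. Genes picked on row C were found in 91.7% of the wells of row D (22 of 24) and in 4 of 334 wells of the other 14 plate rows, as reads of other libraries in whole plate rows could give, for example through shared indexes. The wells belonged to all 6 sorted groups of the row, which sorted cells of another type would not give. The genes were first picked without a limit on their rarity, which gave 100% of row D and 47.3% of the other wells. No biological explanation was tested, and leaving these plate rows out left the counts of genes at 85, 251 and 9 in mesenchymal-like cells, 28, 84 and 3 in endothelial-like cells, and 6 and 52 for the difference between classes. Of the 48 kept cells of these plate rows, 36 were in cluster 12, which was unnamed and so entered no sum. Few cells could thus be left out, and counts close to the reported ones could hardly turn out otherwise.

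Other splits of the samples, keeping 1 sum of each number on either side, number 8 per comparison in most classes, so that their share cannot fall under 0.125. Fits to the 8 sums of a comparison gave 50, 77 and 16 genes in mesenchymal-like cells (day 2, day 10 and day 10 against day 2) with 0 in the highest other split, and 3, 1 and 5 in endothelial-like cells with 0 in the highest other. The reported fits, which also hold the sums of the remaining condition, gave 86, 252 and 9 in mesenchymal-like and 28, 90 and 3 in endothelial-like cells. Most endothelial genes at day 2 and day 10 thus passed only in the fit of all conditions. In vascular smooth muscle-like cells the fits to 8 sums gave 56, 53 and 1 genes (124, 113 and 1 in the reported fits). In glomerular-marker cells they gave 1, 35 and 14 (17, 94 and 23 in the reported fits), again with 0 in the highest other split of both subclasses. In pericyte-like cells at day 2 edgeR gave 0 in all 8 splits, the real one included (411 genes at an unadjusted p under 0.05 in the fit of all conditions). Arterial-like cells, and peritubular capillary-like cells at day 2, allow 4 splits, whose share cannot fall under 0.25, and edgeR gave 0 in each, the real ones included (579, 619 and 422 arterial and 373 peritubular capillary genes at an unadjusted p under 0.05 in the reported fits), so these splits do not test the 4 genes of the arterial day 10 comparison. The difference between classes gave 1 gene at day 2 (highest other 1, so that 2 splits gave as many) and 24 at day 10 (highest other 2). For gene lists, the real splits passed 7, 15 and 16 lists in mesenchymal-like cells (highest other 7, 14 and 10) and 17, 9 and 4 in endothelial-like cells (highest other 7, 6 and 5). As many lists came from 3 splits for mesenchymal-like cells at day 2, from 5 splits for endothelial-like cells between the days and from the real split alone, 1 of 8, in the other list comparisons.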

How the results depend on the processing

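Sums per plate, leaving out number 1 or 4, the mouse as block, all cells of a gate, mixed markers at 100 CPM, and leaving out plate rows C and D of plate 1 or fibroblast-like cells were chosen after the data were seen, and the other alternatives before. Of the gene counts under alternatives, 175 stayed within 1.5 times the reported count and 156 did not. Of the changes of named genes, 2450 kept their direction and side of the threshold, 858 kept their direction but no longer passed, 0 passed where they had not, and 12 reversed. Genes of largest change within a class were named only with 1 sign in every number. Leaving out a plate or a number could therefore hardly reverse them, and their kept direction there is not a separate result. The tests miss small changes: on simulated data, 15.6% of genes with a 2-fold change and a mean log2 CPM of at least 4 were recovered in mesenchymal-like cells at day 2. Counts are given in the order day 2, day 10, and day 10 against day 2, the last of which the difference between classes lacks, and where no reason is named, the cause was not tested.

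The DESeq2 Wald test passed 558, 1076 and 374 in mesenchymal-like cells, 446, 705 and 261 in endothelial-like cells, 358 and 592 for the difference between classes, 564, 639 and 162 in vascular smooth muscle-like cells, and 417, 653 and 337 in glomerular-marker cells. DESeq2 size factors in the edgeR fit moved only the day 2 difference between classes, to 3. Without a filter on low counts the counts were 135, 344 and 39 in mesenchymal-like cells, 68, 163 and 19 in endothelial-like cells, 9 and 50 for the difference between classes, 141, 151 and 7 in vascular smooth muscle-like cells, and 33, 137 and 46 in glomerular-marker cells. Without the block they were 53, 113 and 3 in mesenchymal-like cells, 20, 42 and 2 in endothelial-like cells, 2 and 26 for the difference between classes, 87, 82 and 1 in vascular smooth muscle-like cells, and 25, 82 and 24 in glomerular-marker cells. Sums per plate, which add sums but treat plates of 1 number as separate, gave 163, 475 and 56 in mesenchymal-like cells, 124, 292 and 49 in endothelial-like cells, 32 and 157 for the difference between classes, 199, 213 and 7 in vascular smooth muscle-like cells, and 95, 251 and 87 in glomerular-marker cells. Cells thinned to 20000 reads, which weighs cells equally, gave 145, 405 and 58 in mesenchymal-like cells, 82, 175 and 25 in endothelial-like cells, and 10 and 76 for the difference between classes. At least 2000 genes per cell gave 12 for the day 2 difference between classes, at least 500 genes and 5000 reads 30 for the day 10 difference, and all cells of the gate 11 for the day 2 difference. At least 20 cells per sum moved only the arterial day 10 count, to 0 in edgeR (461 at an unadjusted p under 0.05). Without fibroblast-like cells the counts were 82, 103 and 1 in mesenchymal-like cells, and those of the difference between classes 7 and 8. Without cells of mixed markers at 1 read, which left 485 of 2009 cells, edgeR passed 0, 0 and 0 in mesenchymal-like cells, 0, 0 and 0 in endothelial-like cells, and 8 and 10 for the difference between classes, with 325, 346, 179, 681, 701 and 419 genes at an unadjusted p under 0.05 in the 6 class comparisons. At 100 CPM, which left out 202 cells, the endothelial day 10 against day 2 count was 1.

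Pericyte-like (day 2), arterial-like and peritubular capillary-like cells (day 2) were not tried with other limits per cell, thinned cells, all cells of the gate, or cells of mixed markers or plate rows C and D of plate 1 left out. The DESeq2 Wald test passed 232 in pericyte-like, 347, 431 and 264 in arterial-like and 454 in peritubular capillary-like cells, and no filter on low counts gave 1, 7, 7 and 2, and 22. Sums per plate gave 1 gene in pericyte-like cells, and no block 2 at day 10 in arterial-like cells. The arterial day 10 count was 0 in edgeR without number 1 or 4 (506 and 372 at an unadjusted p under 0.05) and ranged from 0 to 5 with a plate left out, at 0 without plates 1, 2 and 4 (608, 506 and 471 at an unadjusted p under 0.05). The peritubular capillary day 2 count ranged from 0 to 1 with a plate left out (edgeR, 395 at an unadjusted p under 0.05 without plate 1) and was 3 without number 4, and at least 20 cells per sum gave no value there.

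Without number 1 the counts were 38, 69 and 2 in mesenchymal-like cells, 3, 11 and 2 in endothelial-like cells, 1 and 10 for the difference between classes, 48, 61 and 0 in vascular smooth muscle-like cells, and 1, 20 and 2 in glomerular-marker cells, and without number 4 32, 53 and 4 in mesenchymal-like cells, 0, 6 and 0 in endothelial-like cells, 0 and 3 for the difference between classes, 40, 33 and 0 in vascular smooth muscle-like cells, and 0, 14 and 2 in glomerular-marker cells. Of these, the counts of 0 in edgeR had 615 genes (vascular smooth muscle-like, without number 1) and, without number 4, 856, 675, 1148, 665 and 723 at an unadjusted p under 0.05 in the order of the text. With the mouse as block the difference between classes gave 0 and 3 genes, with 810 at an unadjusted p under 0.05 at day 2. Leaving out each plate in turn gave counts from 35 to 76, 40 to 234 and 0 to 10 in mesenchymal-like cells, from 4 to 22, 15 to 85 and 1 to 7 in endothelial-like cells, from 3 to 6 and 7 to 56 for the difference between classes, from 39 to 124, 38 to 108 and 0 to 2 in vascular smooth muscle-like cells, and from 0 to 16, 49 to 78 and 5 to 16 in glomerular-marker cells. The lowest, 0 in edgeR, had 949 genes at an unadjusted p under 0.05 in mesenchymal-like cells without plate 4, 712 in vascular smooth muscle-like cells without plate 6, and 849 and 869 in glomerular-marker cells without plates 3 and 6. Plate 4 holds the whole of number 3, and fewer samples alone lower a count.

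Of 31 gene lists, camera with an estimated correlation passed 0 in each of the 6 class comparisons, with 3, 12, 7, 4, 3 and 2 at an unadjusted p under 0.05. Fry passed 3, 13 and 6 lists in mesenchymal-like cells and 0, 0 and 0 in endothelial-like cells, with 9, 12 and 3 at an unadjusted p under 0.05 in the latter. The correlations of the day 2 and day 10 changes were 0.272 and 0.207 with separate healthy sums, where each day also used fewer numbers.

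Day 10 differences in the share of cells reversed for glomerular-marker cells at 2000 genes (-5.56 points) and for peritubular capillary-like cells at 2000 genes (16.3) and Leiden resolution 1.5 (5.86). Day 2 differences, within their spread, reversed for mesangial-like cells at 500 genes (0.444) and vascular smooth muscle-like cells at resolution 0.5 (0.47). With a plate left out, day 2 differences ranged from -0.882 to 9.47 for glomerular-marker cells, -0.175 to 1.65 for fibroblast-like cells and -3.8 to 1.32 for pericyte-like cells. The day 2 difference in endothelial-like cells with a proliferation signature was -0.771 points when 2 genes were enough. Over the 6 plates, exact sign-flip tests reached 0.03125, the smallest p they can give, for fibroblast-like (13.5 points), glomerular-marker (19.5) and peritubular capillary-like cells (-10.8) at day 10 and for the log2 ratio of gene to ERCC reads in mesenchymal-like cells at day 2 (0.33) and endothelial-like cells at day 10 (0.23), with plates of 1 number counted apart. The other 216 values of such differences kept their direction, and most of them could not have passed 0.05, since 4 numbers allow no p under 0.125.

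Without cells of mixed markers at 1 read, Acta2 (0.069, mesenchymal, day 2 against healthy), Nhsl2 (1.63, mesenchymal, day 10 against healthy), Pdgfrb (0.46, mesenchymal, day 10 against healthy), Pecam1 (0.15, endothelial, day 2 against healthy) and Hmbox1 (1.81, difference between classes, day 10) reversed. Without cells of mixed markers at 100 CPM, Pdgfrb (0.026, mesenchymal, day 10 against healthy) reversed. Without fibroblast-like cells, Spp1 (-3.34, mesenchymal, day 10 against day 2) and Nkd2 (-4.61, mesenchymal, day 10 against healthy) reversed. With a plate or a number left out, the change of Col1a1 (mesenchymal, day 2 against healthy) ranged from -0.11 to 1.08. With a plate or a number left out, the change of Pecam1 (endothelial, day 2 against healthy) ranged from -0.084 to 0.029.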

Other observations

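Lists of immune-related genes had positive median changes in mesenchymal-like cells at day 10, with few members past the threshold. Fibroblast-like cells in these sums numbered 11 in healthy kidneys and 62 at day 10, and the lists were not tested without them. Of 15 chemokine and cytokine genes, 1 rose, 0 fell and 14 did not pass. When adjusted over the list alone, 3 rose and 0 fell. Its median change was 1.92 (camera adjusted p = 0.000386, and adjusted p = 0.14 with an estimated correlation), with Cx3cl1 at 2.22 ± 0.41. Of 21 interferon response genes, 0 rose, 0 fell and 21 did not pass. Adjusted over the list alone, 2 rose and 0 fell, and the median change was 1.16 (camera adjusted p = 7.10e-05, and adjusted p = 0.0729 with an estimated correlation). Of 8 complement genes, 2 rose, 0 fell and 6 did not pass. With p adjusted over the list alone, 5 rose and 0 fell, and the median change was 0.97 (camera adjusted p = 0.000133, and adjusted p = 0.102 with an estimated correlation), with Serping1, which inhibits the first steps of the classical pathway, at 0.74 ± 0.15. Bmp1, which cleaves procollagen, and Tgfbr2, a receptor of transforming growth factor beta, were at 1.68 ± 0.24 and 2.09 ± 0.35. Each of these named genes passed and was higher in 4 of 4 numbers.

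In endothelial-like cells at day 10, of 18 NF-kB target genes, 0 rose, 0 fell and 18 did not pass. The median change was 0.82 (camera adjusted p = 0.0013, and adjusted p = 0.388 with an estimated correlation), and adjusted over the list alone 6 rose and 1 fell. Of 15 matrix protease and inhibitor genes, 1 rose, 0 fell and 14 did not pass. When adjusted over the list alone, 7 rose and 1 fell. Its median change was 1.08 (camera adjusted p = 0.00383, and adjusted p = 0.388 with an estimated correlation). The unfolded protein response list was higher in mesenchymal-like cells at day 2 (median 0.44, adjusted p = 2.78e-08 and, with an estimated correlation, 0.251). Ldha, a subunit of lactate dehydrogenase, was at 1.4 ± 0.13 log2, adjusted p = 0.000922 at day 2 and 0.85 ± 0.13 log2, adjusted p = 0.0106 at day 10 in mesenchymal-like cells, higher in 4 of 4 numbers each time.

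Some sorted cells were neither mesenchymal-like nor endothelial-like. Cells with distal nephron and collecting duct markers numbered 2, 1 and 18 in the mesenchyme gate of healthy, day 2 and day 10 kidneys, and cells with podocyte markers 5, 19 and 15. Cells with proximal tubule markers in the endothelia gate numbered 10, 3 and 0. In edgeR tests of cell numbers, chosen after the shares were seen, distal nephron-like cells in the mesenchyme gate at day 10 had a log2 change 2.85, adjusted p = 0.00887, and proximal tubule-like cells in the endothelia gate a log2 change -4.34, adjusted p = 0.0203.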
